A study of Capra hircus with 72 samples.

How the data were processed

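RNA-seq libraries were made from blood and muscle of intact male Spanish goats (Capra hircus) that were held in pens as controls or transported in a livestock trailer for 30 min or 180 min. The design text describes 54 goats, 18 for each treatment, handled on a pair of days, and no label assigns a day to a library. Per the labels' protocols, blood RNA was isolated with a MagMAX kit for stabilized blood tubes, muscle RNA with an RNeasy Fibrous Tissue kit, and libraries were prepared with the NEBNext Ultra RNA kit. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so gene coordinates are printed as the deposited tables list them, without a named build. Whether counting used strand is likewise not given in the sources used here, so genes with near-identical copies or overlapping neighbours, such as ribosomal protein genes and mitochondrially encoded genes, carry uncertain counts.

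The 72 libraries were grouped by the treatment in their titles and group tags. The blood set held 7 control, 4 libraries of 30 min and 7 of 180 min transport. Muscle was sequenced as a pair of sets with 9 libraries in each group, which the deposited tables mark 24H and 6D. The labels do not define these marks and they are used here only as names of the sets. The libraries carry goat numbers from 1 to 27 only, fewer than the goats the design text describes. Goats with the same number occur in several sets, so the sets do not add independent goats. For muscle goat 9 the title and the group tag say control while the treatment and description fields name 180 minutes of transport. It was treated as control, and counts without it are given.

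Each of 6 deposited tables compared one transport group with the controls of the same set. In the deposited tables the normalized counts are a signal, gene counts that the authors divided by one size factor per library, separately for each table; this was checked on the values. Raw counts per gene were deposited beside them and are whole numbers, per the file headers. The authors also deposited FPKM values, which per the values are counts scaled by the listed gene length in bases and by the library total. The log2 fold change, the p-value and the adjusted p-value of each gene are the authors' own, and the tool behind them is not given in the sources used here. Every gene in the deposited tables had an unadjusted p-value under 0.05, so each table is a selection of genes made on the comparison it describes. The number of genes the authors adjusted over was recovered by inverting the Benjamini-Hochberg formula. With it the deposited adjusted p-values were matched to a relative tolerance of 1e-06 for 31 of 430 genes in the blood 30 min table, where the rest lay on one shared value that genes outside the table can set. They were matched for 846 of 849, 3912 of 3912, 1872 of 1874, 1252 of 1252 and 1547 of 1547 genes in the blood 180 min, muscle 30 min 24H, muscle 180 min 24H, muscle 30 min 6D and muscle 180 min 6D tables. Genes listed with an adjusted p-value of exactly 1 were taken as not adjusted. The library total implied by the FPKM columns ranged from 9.45 to 39.5 M counts (M for 1e+06) per library, with a median of 14.7 M. These totals set the counting error of low genes, and the spread between goats was measured directly from the replicates.

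The tests, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. The planned test for a table of selected genes was limma (version 3.58.1, with trend) on log2 of the normalized counts plus 1, with Benjamini-Hochberg adjustment within the table at a threshold of 0.05. Because the genes were selected on the same comparison, this adjusted p describes the table and is not an independent test. The added 1 shrinks the change of genes with low counts. A difference between means of log2 values can still be larger or smaller in size than the authors' log2 fold change. The planned tests of all genes with TMM scaling, expression filtering and set tests against unlisted genes were not applicable to selected genes. After the data were seen, limma, the edgeR quasi-likelihood test (version 4.0.16) and the DESeq2 Wald test (version 1.42.0) were also run on the listed genes. They used the authors' size factors and were adjusted over the number of genes the authors had adjusted. Listed genes taken as not adjusted by the authors were tested too, so the counts are not on exactly the authors' genes. In a direct test of 180 min against 30 min, log2 of counts per M of the library total plus 0.5 was used. The edgeR and DESeq2 dispersions were estimated on the listed genes alone. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

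In the report a gene is called when its adjusted p in the authors' deposited table was under 0.05. It is said to have risen or fallen when it was called and the limma adjusted p within the table was also under 0.05. Errors of log2 changes are standard errors from limma, errors of normalized counts are standard deviations, and n is the number of goats. Goats differ between groups, so no pairing enters the comparisons with control. Goats of a group were treated as independent, and the labels give no day, batch or other covariate per goat. A trip, pen, handling order or sampling time shared within a group could therefore not be told apart from transport. The named-gene rule took called genes with a symbol, a mean of at least 50 normalized counts and group medians on the side of the fold change. It took the 6 largest rises and the 6 largest falls, up to 4 members of each list with 3 or more called members, and a set of well-known stress genes wherever listed. A few genes that the rule chose are left out of the text and were not replaced, and they stay in all counts of genes and lists. Further members of a list given as examples were chosen after their values were seen, and are marked so.

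The 37 gene lists covered stress responses, energy metabolism, muscle structure, proteolysis, immune responses and cell type markers. For each list with at least 5 members in a table, Fisher's exact test (two-sided) compared the split of its members into higher and lower with that of the other listed genes, with Benjamini-Hochberg adjustment over the lists of that table. This compares directions among selected genes and says nothing of enrichment against genes outside the table. Members of one list can vary together across the same goats, so these p-values describe splits of genes that are not independent. Counts adjusted over the list alone use the authors' unadjusted p-values and the full size of the list. Overlaps of 30 min and 180 min tables, which share control libraries, were set beside simulations of unchanged groups against shared controls (200000 genes). They were also set beside the overlap of independent lists and beside 20 splits of the controls. The overlap of independent lists was the product of both list sizes divided by the smaller number of genes adjusted in either table. The simulated share of genes was multiplied by that same smaller number.

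The other settings fixed beforehand were the authors' adjusted p, an adjusted p of 0.01, an absolute log2 change of at least 1, a mean of at least 10 normalized counts, pseudocounts of 0.5 and 5, scaling to the total or the upper quartile of the listed genes, an exact Wilcoxon rank test, leaving out each goat in turn, list members with a mean of at least 50, and the goat number as a block across muscle sets. Scaling to the library total, the tests adjusted over all genes, DESeq2 with each goat left out and the direct comparison of 180 min with 30 min were added after the data were seen. In muscle, libraries of the same goat number deviated together between the sets, with a median correlation over genes of 0.503 in the 30 min comparison (lowest -0.19, over 0.1 in 14 of 18 goats) and 0.599 in the 180 min comparison (lowest 0.312, over 0.1 in 18 of 18 goats), against medians of -0.07 and -0.08 between different numbers. The correlation was highest with the own number in 11 of 18 goats in the 30 min comparison and 17 of 18 in the 180 min comparison. The numbers are goat numbers in the labels, so the pairing comes from the labels and is not settled by these correlations. The tests were tried on simulated data with known changes. In the simulated muscle 30 min 24H table (4125 genes), limma recovered 88% of genes changed 2-fold and 98% of genes changed 4-fold. In the simulated blood 180 min table (1247 genes) it recovered 5% and 49%, and in the simulated blood 30 min table (430 genes) 16.7% and 50.7%. Unchanged genes made up 5.10%, 8.47% and 5.88% of those past the threshold by limma in these 3 simulated tables, in the order given. By DESeq2 they made up 10.6%, 5.26% and 11.4%. The RefSeq gene table supplied with the genome was not used here.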

Results

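Blood and muscle transcriptomes were compared between goats held in pens and goats transported for 30 min or 180 min, to ask how the stress of transport bears on gene expression in tissue relevant to meat quality. The blood control libraries held a median of 20.6 M counts (M for 1e+06; range 10.4 to 39.5 M), the 30 min libraries 19.4 M and the 180 min libraries 26.1 M. The muscle libraries of the 24H set had medians of 14.7 M in controls, 16.2 M at 30 min and 14.7 M at 180 min, and those of the 6D set 13, 13.2 and 12.6 M. Each deposited table lists only genes selected at an unadjusted p under 0.05, so the counts of higher and lower genes describe that selection.

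In blood after 30 min of transport, 5 genes were called and all of them rose. NFKBIA, the inhibitor that retains NF-kB in the cytoplasm (ENSCHIG00000010157, chromosome 21, 45051852 to 45054610), rose from 754 ± 151 normalized counts (SD, n = 7) to 2445 ± 741 (n = 4), a log2 change of 1.68 ± 0.24 (SE, limma adjusted p = 0.002). SOCS1, a feedback inhibitor of cytokine signalling, rose by 2.56 ± 0.40 from 74.3 ± 32.0 to 422 ± 153. GADD45A, a stress-inducible growth arrest gene, and CEBPB, a transcription factor of myeloid and acute-phase responses, each rose by 1.43 with errors of 0.24 and 0.25. CXCR4, a chemokine receptor of leukocytes, rose by 1.19 ± 0.22, from 1537 ± 390 to 3401 ± 208. Each of the 5 genes was above the control median in 4 of 4 transported goats.

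The glucocorticoid response list, genes induced by cortisol-type hormones through their nuclear receptor, had 10 members in the blood 30 min table and all 10 were higher in transported goats. The other genes of the table split into 117 higher and 303 lower (Fisher's exact test, adjusted p = 1.6e-05 over 4 lists). Of these members 2 were called, 7 passed limma within the table and 8 passed when adjusted over the list alone. Without 30 min goat 21, 3 members passed limma, and without 30 min goat 24, 4 did. DDIT4 (1.76 ± 0.35, limma adjusted p = 0.0092) and SGK1 (1.34 ± 0.29, adjusted p = 0.014), both chosen as examples after their values were seen, were not called. TSC22D3, a glucocorticoid-induced leucine zipper gene, had a log2 difference of 0.91 ± 0.23 and was not called. Immediate early genes, transcribed within minutes of a stimulus, were listed as 7 higher and 1 lower (adjusted p = 0.0021, 0 called by the authors, 2 past limma within the table, 3 adjusted over the list alone). Of the 2, 0 passed limma without 30 min goat 21, 30 min goat 24 or control goat 3, and 1 without 30 min goat 22, 30 min goat 27 or control goat 1. FOS among them had 727 ± 464 normalized counts against 264 ± 80.1 (log2 difference 1.34 ± 0.33) and was not called. Hypoxia genes were listed as 4 higher and 1 lower (adjusted p = 0.038, 0 called, 1 past limma and 1 adjusted over the list alone). B cell markers were listed as 0 higher and 6 lower, a split not different from that of the other genes (adjusted p = 0.19, 0 called, 0 past limma and 0 adjusted over the list alone).

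In total the authors' deposited table of blood at 30 min listed 430 genes, 127 higher and 303 lower, out of 20719 adjusted, of which 5 had an adjusted p under 0.05. With no effect, about 1036 of 20719 genes would have an unadjusted p under 0.05. Within the table limma passed 19 genes, 18 higher and 1 lower (94.7% higher; exact binomial p = 7.6e-05, a description across genes that are not independent). With adjustment over all 20719 genes DESeq2 called 6 genes, while edgeR and limma called 0, with 305 and 216 of the 430 genes at an unadjusted p under 0.05. The number of limma genes was 7 without 30 min goat 21, 10 without 30 min goat 24 and 12 without control goat 1.

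In blood after 180 min of transport, the largest rises among the genes named here were those of PTX3 and IL1R2. IL1R2, the decoy receptor for interleukin 1 (ENSCHIG00000024086, chromosome 11, 6611209 to 6650345), rose from 117 ± 84.8 (SD, n = 7) to 3466 ± 3179 normalized counts (n = 7), a log2 change of 4.57 ± 0.65 (SE, limma adjusted p = 0.0011). PTX3, a secreted pattern recognition protein (chromosome 1, 109705569 to 109711190), rose by 5.51 ± 0.81 from 349 ± 406 to 19112 ± 23317. SLC26A8, an anion transporter gene, rose by 3.46 ± 0.50, CLEC4E, a lectin receptor for microbial glycolipids, by 3.29 ± 0.48 and IL18RAP, a subunit of the interleukin 18 receptor, by 3.20 ± 0.57. Each of these 5 genes was above the control median in 7 of 7 transported goats. In the other direction PTGR1, a prostaglandin reductase, fell by 1.32 (SE 0.30). TNFRSF25, a death receptor of lymphocytes, fell by 1.05 (SE 0.24), and INHBB, an activin subunit gene, fell by 2.5 (SE 0.72), although INHBB no longer passed without one of the goats (limma adjusted p up to 0.064).

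Neutrophil markers were listed as 12 higher and 0 lower against 729 and 506 among the other genes (Fisher's exact test, adjusted p = 0.029 over 14 lists), with 2 called, 6 past limma within the table and 7 adjusted over the list alone. ALPL, the alkaline phosphatase of mature neutrophils, rose by 4.02 ± 0.84 from 166 ± 214 to 1805 ± 1597. Examples chosen after their values were seen, S100A12 (1.74 ± 0.54), PGLYRP1 (2.46 ± 0.59) and LTF (2.46 ± 0.63), passed limma within the table at adjusted p of 0.037, 0.017 and 0.024. T cell and NK cell markers were listed as 1 higher and 8 lower (adjusted p = 0.029), with 1 called in each direction, 6 past limma and 6 adjusted over the list alone. LCK, the kinase that starts T cell receptor signalling, fell by 0.73 (SE 0.19), from 2432 ± 470 to 1453 ± 199, and was lower in every transported goat than the control median, but no longer passed without one of the goats (limma adjusted p up to 0.058). The exception was NKG7 at 0.88 ± 0.22, a cytotoxic granule gene named after its value was seen. Among genes with a mean of at least 50 normalized counts the neutrophil split, still 12 higher and 0 lower, no longer passed (adjusted p = 0.11), and the T cell and NK cell split did (adjusted p = 0.0053). Of the lymphocyte markers listed as lower, 5 passed limma in all goats and 0 did without control goat 4 or control goat 6. The number was 1 without control goat 1 or 180 min goat 15 or 16, and 2 without control goat 7 or 8 or 180 min goat 11. Of the neutrophil markers 3 passed without control goat 1, 4 or 6 or without 180 min goat 15 or 16. Normalized counts of blood are relative across its cell types, and no cell shares entered the comparison. Different shares of cells and changes within cells can therefore not be told apart for the lymphocyte markers. The same holds for the other blood genes named here, such as IL1R2, PTX3 and TNFRSF25.

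Glucocorticoid response genes were listed in this table as 10 higher and 2 lower, a split that did not differ from that of the other genes (adjusted p = 0.32, 5 called, 6 past limma, 6 adjusted over the list alone). Besides IL1R2, the called members GLUL, the glutamine synthetase gene (1.78 ± 0.37), DDIT4, an inhibitor of mTOR signalling (1.62 ± 0.33), and CEBPD (1.59 ± 0.33) rose. The clock gene PER1 had 597 ± 433 against 198 ± 85.4 normalized counts, CAPN1, which encodes a calpain protease, 10865 ± 6850 against 6045 ± 2082, and FOS 721 ± 687 against 299 ± 108, and none of these 3 was called. Innate sensing and NF-kB genes were listed as 8 higher and 0 lower (adjusted p = 0.11, 1 called, 5 past limma, 2 adjusted over the list alone).

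The authors' deposited table of blood at 180 min listed 1247 genes, 741 higher and 506 lower. Of these, 398 were taken as not adjusted and so as outside the 9944 genes adjusted. An adjusted p under 0.05 was given for 63 higher and 7 lower genes. Within the table limma passed 355 genes, 258 higher and 97 lower (72.7% higher, exact binomial p = 5.4e-18). The share higher was 8.79% with libraries scaled to the total of the listed genes, which held 13 ± 6.19% of a transported library and 6.60 ± 2.08% of a control library. It was 15.5% with the upper quartile of the listed genes, for which the cause was not tested. Adjusted over 9944 genes DESeq2 called 127, edgeR 8 and limma 9, with the 398 genes taken as not adjusted by the authors tested too. The 355 limma genes became 65, 76, 82, 78, 94, 116 and 163 without control goat 4, control goat 6, 180 min goat 15, 180 min goat 16, control goat 1, 180 min goat 11 and control goat 8.

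**Figure D1:**
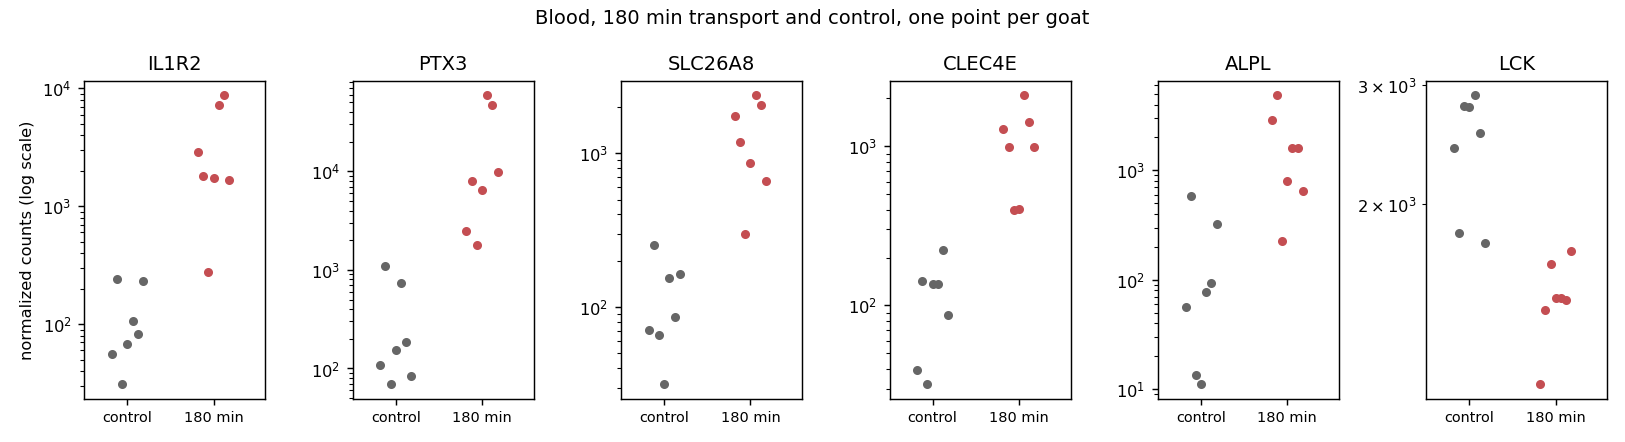
Normalized counts (log scale) of 6 genes in blood, one point per goat for 7 control goats and 7 goats transported for 180 min. Every transported goat lies above the control median for IL1R2, PTX3, SLC26A8, CLEC4E and ALPL and below it for LCK.

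In muscle after 30 min of transport, 24H set, FKBP5, a co-chaperone that restrains the glucocorticoid receptor and is induced by it (ENSCHIG00000014746, chromosome 23, 39071133 to 39140144), rose from 567 ± 110 normalized counts (SD, n = 9) to 1657 ± 504 (n = 9), a log2 change of 1.52 ± 0.17 (SE, limma adjusted p = 2.6e-05), and was above the control median in 9 of 9 transported goats. LIPG, the endothelial lipase gene (chromosome 24, 49368520 to 49422243), rose by 1.96 ± 0.31 and NCEH1, a cholesteryl ester hydrolase gene, by 1.72 ± 0.30. Further large rises were ZYG11B (1.69 ± 0.43), PPTC7 (1.54 ± 0.36), a mitochondrial phosphatase gene, and ELL2 (1.31 ± 0.35), a transcription elongation factor gene. The largest falls included ND1, a mitochondrially encoded subunit of complex I, with a log2 change of -1.47 ± 0.34, the adaptor gene STAP2 at -1.30 ± 0.28 and MDK, which encodes the growth factor midkine, at -1.27 ± 0.42. The immediate early gene FOSB was called but at 67.1 ± 57.0 against 309 ± 404 normalized counts did not pass limma (adjusted p = 0.12).

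Nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were listed as 0 higher and 31 lower in this table. The other genes split into 2023 higher and 2071 lower (Fisher's exact test, adjusted p = 2.6e-08 over 27 lists, across genes that are not independent). Of the oxidative phosphorylation genes 25 were called, 29 passed limma and 28 were past the threshold adjusted over the list alone. COX5B, a subunit of cytochrome c oxidase, fell by 0.77 (SE 0.19), from 16729 ± 4805 to 9851 ± 2796, and the complex I subunit NDUFB7 fell by 0.62 (SE 0.17). Cytosolic ribosomal protein genes were listed as 0 higher and 23 lower (adjusted p = 3.3e-06, 15 called, 23 past limma, 21 adjusted over the list alone), including RPS29 (-0.87 ± 0.19). Other short genes were lower too. Both lists together had a median log2 change of -0.48, and random lists of the other listed genes matched on gene length had a median of -0.39. Mitochondrially encoded genes were listed as 0 higher and 10 lower (adjusted p = 0.0066, 6 called, 9 past limma, 6 adjusted over the list alone), with ND5 at -0.96 ± 0.25. Without 30 min goat 23, or without control goat 7, 22 oxidative phosphorylation genes and 12 ribosomal protein genes passed limma. The ribosomal protein genes numbered 13 without 30 min goat 19 or control goat 5, and 14 without 30 min goat 20 or control goat 9. In the library of control goat 7 the listed genes held 69.4% of all counts, against 52.4 ± 7.67% over the 9 controls and 46.0 ± 3.33% over the 9 transported goats.

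Several signalling and contractile groups were on the higher side of the same table. Log2 change rose with gene length over its genes (Spearman rho = 0.23 across genes, which are not independent), and these groups were not matched on length. Insulin and growth signalling genes were listed as 14 higher and 0 lower (adjusted p = 0.00041, 10 called, 13 past limma, 13 adjusted over the list alone). Among them PIK3R1, a regulatory subunit of PI3 kinase, rose by 1.08 ± 0.21, and the transcription factor gene FOXO3 by 1.30 ± 0.33. Calcium handling genes were listed as 11 higher and 0 lower (adjusted p = 0.0021, 9 called, 9 past limma, 9 adjusted over the list alone). CACNA2D1, a calcium channel subunit gene, rose by 1.02 ± 0.25 and PPP3CA, the calcineurin catalytic subunit gene, by 0.88 ± 0.23. Glucocorticoid response genes were listed as 13 higher and 1 lower (adjusted p = 0.0036, 8 called, 14 past limma, 12 adjusted over the list alone), among them ZBTB16 (1.12 ± 0.24) and KLF9 (1.05 ± 0.26). TSC22D3 was called in this table and rose by 0.47 ± 0.16, from 2412 ± 345 to 3452 ± 1052 (limma adjusted p = 0.025). Circadian clock genes were listed as 9 higher and 1 lower (adjusted p = 0.028, 4 called, 9 past limma, 9 adjusted over the list alone), with HLF at 0.99 ± 0.27 and BHLHE41 at 1.17 ± 0.32. Glycogen metabolism genes were listed as 8 higher and 1 lower (adjusted p = 0.042, 5 called higher and 1 lower, 8 past limma, 7 adjusted over the list alone). GAA, the lysosomal glucosidase gene, rose by 0.69 ± 0.17. Hypoxia genes were listed as 7 higher and 0 lower (adjusted p = 0.02, 4 called, 5 past limma, 4 adjusted over the list alone), and sarcomere and cytoskeleton genes as 8 higher and 1 lower (adjusted p = 0.042, 5 called, 6 past limma, 5 adjusted over the list alone). PFKFB4 rose by 0.80 ± 0.21 and VCL, the vinculin gene, by 0.87 ± 0.23. Without 30 min goat 23, 3 clock genes and 4 of the 7 glycogen genes listed as higher passed limma. Clock genes numbered 4 without 30 min goat 19 or control goat 7 or 9, and 5 without 30 min goat 20 or 27 or control goat 2 or 5. Hypoxia genes numbered 3 without 30 min goat 19 or 23 or control goat 7 or 9, and sarcomere genes 3 without control goat 7.

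Some response genes and markers of vascular cells and slow fibres were mostly listed as lower in the same muscle libraries. Interferon-stimulated genes were listed as 0 higher and 14 lower (adjusted p = 0.00083, 9 called, 12 past limma, 12 adjusted over the list alone), with IFI35 at -0.67 ± 0.18. Endothelial and mural cell markers were listed as 0 higher and 11 lower (adjusted p = 0.0038, 9 called, 10 past limma, 11 adjusted over the list alone), with ROBO4, a receptor of the vascular endothelium, at -0.93 ± 0.23. Slow muscle fibre genes were listed as 1 higher and 9 lower (adjusted p = 0.042, 3 called, 10 past limma, 7 adjusted over the list alone), with the slow troponin genes TNNT1 and TNNC1 at -1.02 ± 0.32 and -1.01 ± 0.31. Immediate early genes were listed as 1 higher and 9 lower (adjusted p = 0.042, 1 called higher and 2 lower, 2 past limma, 2 adjusted over the list alone). Without 30 min goat 23, or without control goat 7, 2 of the slow fibre genes listed as lower passed limma, where 9 did in all goats, and 3 did without 30 min goat 19 or 20. Of 12 interferon-stimulated genes 6 passed without control goat 9 and 7 without 30 min goat 19. The immediate early genes listed as lower that passed, 1 in all goats, ranged from 0 without 30 min goat 23 or control goat 7 to 4 without 30 min goat 22. They numbered 3 without 30 min goat 24 or control goat 3 or 8, and 2 without control goat 4 or 6. Ubiquitin-proteasome and atrophy genes were listed as 10 higher and 12 lower (adjusted p = 0.94, 7 called higher and 3 lower, 18 past limma, 16 adjusted over the list alone). PDK4, the kinase that limits glucose oxidation, had 44030 ± 33140 against 16472 ± 13458 normalized counts and was not called.

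The authors' deposited table of muscle at 30 min in the 24H set listed 4125 genes, of which 213 were taken as outside the 12649 adjusted. Of the listed genes 1528, 781 higher and 747 lower, had an adjusted p under 0.05. Limma within the table passed 3195 genes, 1657 higher and 1538 lower (51.9% higher, exact binomial p = 0.037), and the upper quartile scaling gave 42.5% higher. The calls depended on the test, since DESeq2 adjusted over all 12649 genes called 1326 while edgeR called 12 and limma 21. The p-values of edgeR for the called genes were a median of 2.68 times the authors'. Over the 4125 listed genes both sets of p-values ranked alike (Spearman rho = 0.963 across genes, which are not independent). The limma count was 1463 without 30 min goat 23, 1478 without control goat 7, 1648 without 30 min goat 19, 1721 without control goat 9, 1904 without 30 min goat 20, 2057 without 30 min goat 21 and 2091 without control goat 5.

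**Figure D2:**
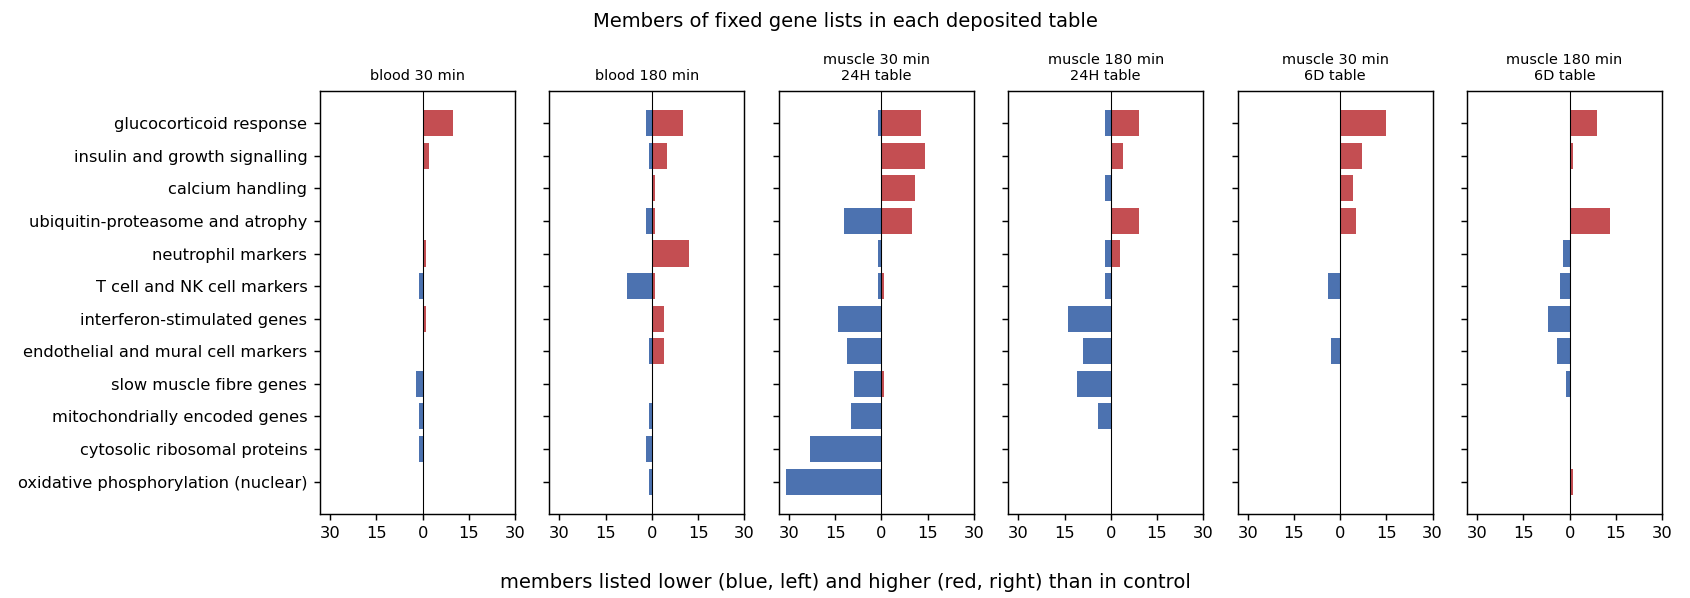
Numbers of members of 12 gene lists that each deposited table lists as higher (red, right) or lower (blue, left) than control, one panel per comparison. For muscle at 30 min in the 24H set, 31 oxidative phosphorylation and 23 ribosomal protein genes lie on the lower side and 0 on the higher side.

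In muscle after 180 min of transport, 24H set, FKBP5 rose by 2.06 ± 0.40 on the log2 scale, from 520 ± 99.3 normalized counts (SD, n = 9) to 2934 ± 2183 (n = 9, limma adjusted p = 0.0043), and was above the control median in 8 of 9 transported goats. PITX3, a homeobox transcription factor gene (chromosome 26, 28794557 to 28805442), rose by 2.43 ± 0.39 from 203 ± 145 to 905 ± 323. ASCC1, a transcriptional coactivator subunit gene (chromosome 28, 17331878 to 17445938), rose by 2.15 ± 0.43 and SLC16A6, a monocarboxylate transporter gene, by 2.13 ± 0.59. SLC7A8, an amino acid transporter gene, rose by 1.49 ± 0.55 but no longer passed without one of the goats (limma adjusted p up to 0.064). Falls were seen for KIAA0408 (-1.37 ± 0.27), for KY, a gene needed for muscle maintenance (-2.07 ± 0.44), and for DDAH1, an enzyme that degrades methylated arginine (-1.48 ± 0.40). PSAT1, a gene of serine synthesis, was called with 45.8 ± 102 against 74.1 ± 88.1 normalized counts, and 180 min goat 10 alone had 317. Its log2 difference of -1.59 ± 0.69 was at the edge of the threshold (limma adjusted p = 0.049), and its adjusted p over all genes was 1 by DESeq2 and 1 by edgeR. ASIP, the agouti signalling gene, was called but had 23.5 ± 45.0 normalized counts against 836 ± 1242 in controls, where 3 of 9 goats held nearly all of it (log2 difference -2.43 ± 1.28, limma adjusted p = 0.078). The cardiac actin gene ACTC1, at 3283 ± 5743 against 512 ± 294, was also called without passing limma (adjusted p = 0.066).

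Interferon-stimulated genes were listed in this table as 0 higher and 14 lower against 954 and 993 among the other genes (Fisher's exact test, adjusted p = 0.001 over 8 lists), with 4 called, 7 past limma and 6 adjusted over the list alone. IFIT1 fell by 1.07 (SE 0.28) and PARP14 by 0.76 (SE 0.22). Slow muscle fibre genes were listed as 0 higher and 11 lower (adjusted p = 0.004, 2 called, 9 past limma, 10 adjusted over the list alone), with the slow myosin heavy chain MYH7 at -0.64 ± 0.23, named after its value was seen. Of these genes 3 passed limma without 180 min goat 12, 4 without 180 min goat 11 or control goat 6, and 5 without control goat 7. Endothelial and mural cell markers were listed as 0 higher and 9 lower (adjusted p = 0.0079, 0 called by the authors, 7 past limma within the table, 5 adjusted over the list alone), and 2 passed limma without 180 min goat 12 or without control goat 3, 6, 7 or 9. The number was 3 without 180 min goat 17 or 18 and 4 without 180 min goat 11 or control goat 1. Ubiquitin-proteasome and atrophy genes were listed as 9 higher and 0 lower (adjusted p = 0.004, 2 called, 2 past limma, 2 adjusted over the list alone). Of them 8 passed limma without 180 min goat 13 and 4 without 180 min goat 16. It was 1 without 180 min goat 11, 12 or 18 or control goat 1, 3, 4, 6 or 9. Glucocorticoid response genes were listed as 9 higher and 2 lower, which did not pass (adjusted p = 0.054, 6 called, 9 past limma, 10 adjusted over the list alone), although CD163, a macrophage scavenger receptor gene (1.55 ± 0.39), CRISPLD2 (0.76 ± 0.21) and FOXO1 (0.87 ± 0.25) rose. TRIM63, a muscle ubiquitin ligase gene, had 4495 ± 3714 against 1997 ± 1343 normalized counts. TSC22D3 had 3827 ± 1855 against 2210 ± 305, and the chaperone gene HSPH1 909 ± 450 against 616 ± 244, and none of these 3 was called.

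The authors' deposited table of muscle at 180 min in the 24H set listed 1961 genes, of which 87 were taken as outside the 14056 adjusted. It held 149 higher and 133 lower genes at an adjusted p under 0.05. Limma passed 1266 genes within the table, 585 higher and 681 lower (46.2% higher, exact binomial p = 0.0076), a split that was 63.9% higher with libraries scaled to the total of the listed genes. Adjusted over all 14056 genes DESeq2 called 273, edgeR 24 and limma 28. The limma count was 562 without 180 min goat 12, 605 without control goat 6, 661 without 180 min goat 18, 696 without control goat 3, 738 without control goat 1 and 748 without control goat 9.

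In muscle of the 6D set, FKBP5 rose after 30 min of transport from 232 ± 92.2 (SD, n = 9) to 697 ± 278 normalized counts (n = 9), a log2 change of 1.56 ± 0.25 (SE, limma adjusted p = 0.0035), in 9 of 9 goats above the control median. LIPG was called with 246 ± 173 against 57.0 ± 39.1 normalized counts (log2 difference 1.99 ± 0.46) but did not pass limma (adjusted p = 0.076). The third called gene, ENSCHIG00000000300, has no symbol in the tables and was lower. Glucocorticoid response genes were listed as 15 higher and 0 lower against 596 and 641 among the other genes (Fisher's exact test, adjusted p = 0.00017 over 9 lists), with 1 called, 1 past limma and 11 adjusted over the list alone. Without control goat 4, 3 of them passed limma. Insulin and growth signalling genes were listed as 7 higher and 0 lower (adjusted p = 0.029, 0 called, 0 past limma and 0 adjusted over the list alone), and genes of fatty acid uptake and oxidation as 6 higher and 0 lower (adjusted p = 0.04, 0 called, 0 past limma, 2 adjusted over the list alone). Among genes with a mean of at least 50 normalized counts the glucocorticoid list alone passed (adjusted p = 0.0011). PDK4, with 20602 ± 20761 against 6492 ± 5045, and PER1, with 3028 ± 1110 against 2021 ± 615 normalized counts, were not called.

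The authors' deposited table of muscle at 30 min in the 6D set listed 1252 genes out of 16947 adjusted, 611 higher and 641 lower, with 3 at an adjusted p under 0.05. Limma passed 1 gene within the table, FKBP5. Adjusted over all 16947 genes DESeq2 called 3 and limma 1, while edgeR called 0, with 946 genes at an unadjusted p under 0.05 by edgeR and 748 by limma. Without control goat 4 limma passed 72 genes within the table, without 30 min goat 24 it passed 6, without 30 min goat 19 or control goat 7 it passed 4, and without control goat 3 it passed 2.

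After 180 min of transport in the 6D set, FKBP5 rose by 1.94 ± 0.29, from 221 ± 87.8 (SD, n = 9) to 917 ± 508 normalized counts (n = 9, limma adjusted p = 0.0022). ASCC1 rose by 2.23 ± 0.42, PITX3 by 2.05 ± 0.36, LIPG by 1.90 ± 0.48 and BAG2, a co-chaperone of HSP70, by 1.5 ± 0.29. KIAA0408 (-1.55 ± 0.31), KY (-1.47 ± 0.40), TSPAN15 (-1.26 ± 0.30), GALNT18 (-1.23 ± 0.31), MDK (-1.20 ± 0.35) and LXN, a carboxypeptidase inhibitor gene (-1.13 ± 0.32), fell, and each of these 6 was above the control median in 0 of 9 transported goats.

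Ubiquitin-proteasome and atrophy genes were listed in this table as 13 higher and 0 lower against 725 and 880 among the other genes (Fisher's exact test, adjusted p = 0.00031 over 9 lists), with 1 called, 4 past limma and 2 adjusted over the list alone. Most of them encode proteasome subunits, such as PSMD12 at 0.42 ± 0.15 and PSMA5 at 0.36 ± 0.14, which were named after their values were seen and were not called. The number past limma was 13 without 180 min goat 15, 9 without control goat 4, 8 without control goat 8 and 7 without 180 min goat 13. It was 2 without 180 min goat 12, 14 or 16, and 1 without 180 min goat 11, 17 or 18 or control goat 3, 5, 6 or 9. Glucocorticoid response genes were listed as 9 higher and 0 lower (adjusted p = 0.0037, 2 called, 7 past limma, 7 adjusted over the list alone), and 3 passed limma without control goat 3. Interferon-stimulated genes were listed as 0 higher and 7 lower, which did not pass (adjusted p = 0.054, 0 called, 1 past limma, 0 adjusted over the list alone). TRIM63 (2566 ± 1892 against 1280 ± 1098 normalized counts), TSC22D3 (1781 ± 703 against 1141 ± 557) and PER1 (2690 ± 1013 against 1926 ± 589) were not called.

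The authors' deposited table of muscle at 180 min in the 6D set listed 1618 genes, of which 71 were taken as outside the 14384 adjusted. It held 62 higher and 57 lower genes at an adjusted p under 0.05. Limma passed 765 genes within the table, 321 higher and 444 lower (42.0% higher, exact binomial p = 9.9e-06). Adjusted over all 14384 genes DESeq2 called 116, edgeR 12 and limma 7. The limma count was 256 without control goat 3, 322 without 180 min goat 18, 410 without control goat 5, 414 without control goat 9, 418 without 180 min goat 12, 427 without 180 min goat 17, 476 without 180 min goat 14, 495 without control goat 6 and 502 without control goat 7.

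**Figure D3:**
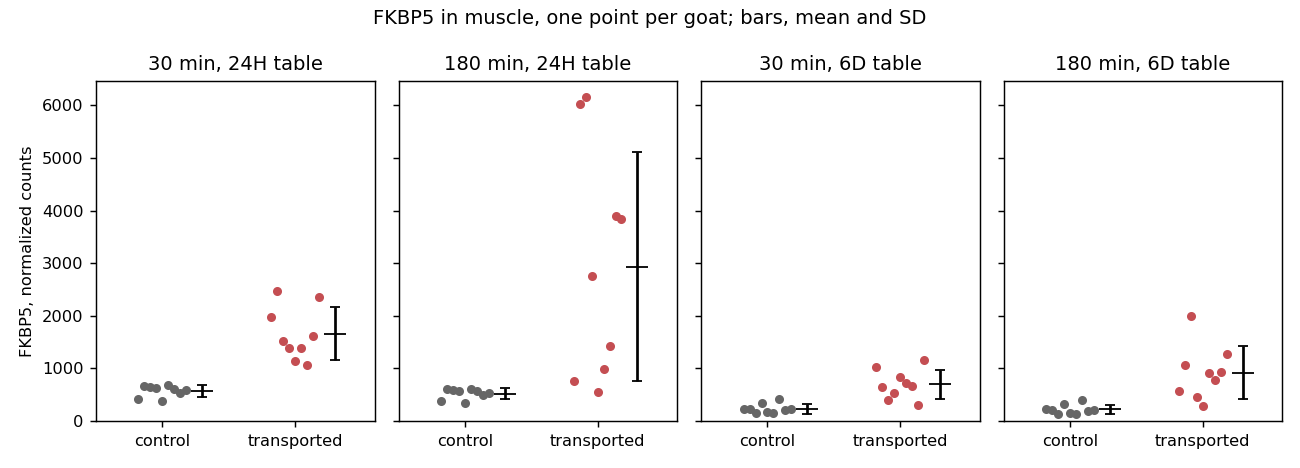
Normalized counts of FKBP5 in muscle, one point per goat, with the mean and SD of 9 control and 9 transported goats beside each group, for 30 min and 180 min of transport in both sets. The group means are 567 and 1657, 520 and 2934, 232 and 697, and 221 and 917 for control and transported goats.

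**Figure D4:**
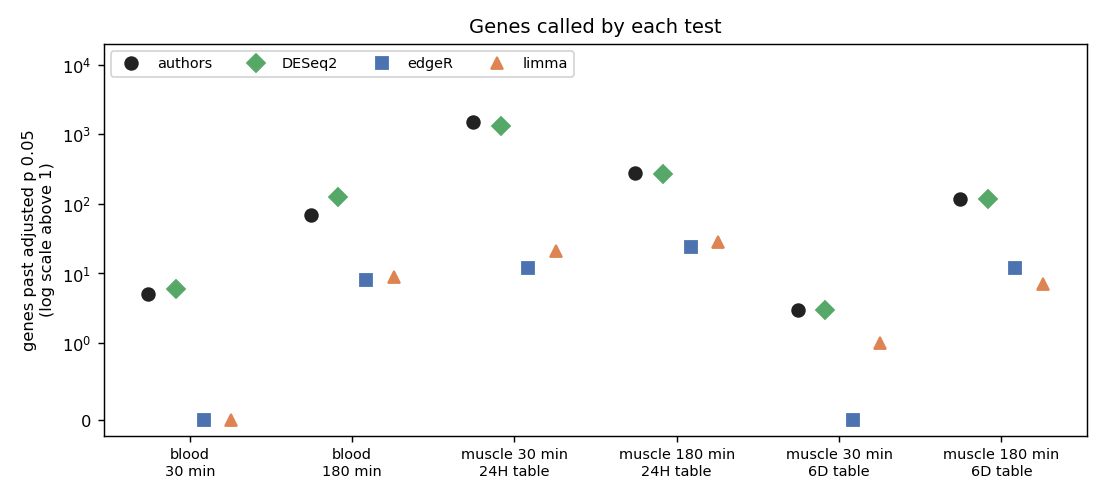
Genes past an adjusted p of 0.05 (log scale above 1) in each comparison by the authors' own test and by DESeq2, edgeR and limma, adjusted over the same number of genes. In the muscle 30 min 24H table the counts are 1528, 1326, 12 and 21.

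The responses to 30 min and 180 min share control libraries. In blood 120 genes were listed in both tables, 116 in the same direction. Independent lists would share 53.9, and unchanged groups against shared controls would share 80.4 with 98.0% in the same direction. Both numbers rest on 9944 genes, while the 30 min table was adjusted over 20719. More genes would raise the simulated number, so 120 is not shown to exceed it. The simulation listed genes at p under 0.05, while 2.08% of the genes adjusted were listed in blood at 30 min. With the controls split between the comparisons a median of 95.8% had the same direction. None was called in both, where independent lists would share 0.0352. In muscle of the 24H set 636 genes were listed in both, 607 in the same direction (independent lists 640, unchanged groups 113 with 99.6% in the same direction, split controls 95%). The 64 genes called in both all had the same direction, 32 higher and 32 lower, where independent lists would share 9.20 and 7.85. In the 6D set 352 were listed in both, 349 in the same direction (independent lists 141, unchanged groups 136 with 99.7%, split controls 98.7%), and 2 were called in both. The simulated values leave out real effects and the independent lists leave out the shared controls, so neither excess measures a shared effect. The controls were split only for genes already listed in both tables with all controls included. That selection had largely set their directions, so the split shares do not show agreement free of the shared controls.

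A direct test of 180 min against 30 min with limma was added after the data were seen and run on genes listed in both tables. In blood 0 of 120 genes differed (5 at an unadjusted p under 0.05) and in muscle of the 6D set 0 of 352 (13 at an unadjusted p under 0.05). Listing in both tables, nearly always in the same direction, had largely selected such differences out, so these counts do not show that both times were alike. In muscle of the 24H set 26 of 636 genes differed. PITX3 and BAG2 were higher at 180 min than at 30 min, by 1.06 ± 0.29 and 0.89 ± 0.20 (adjusted p = 0.038 and 0.01), with rises over control of 1.27 and 0.62 at 30 min and 2.33 and 1.52 at 180 min. The other 24 genes had opposite directions at 30 min and 180 min. A gene listed in both tables at an unadjusted p under 0.05 in opposite directions must differ between the times, so these 24 were largely settled by the selection. Among them SYNE2, a nuclear envelope protein gene, was 0.30 above control at 30 min and -0.55 relative to control at 180 min.

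Between the muscle sets, 647 genes were listed in both 30 min tables, 645 in the same direction (independent lists 408), and 709 in both 180 min tables, 709 in the same direction (independent lists 226). Of the genes called at 180 min, 64 were called in both sets and all 64 had the same direction, where independent lists would share 2.39. The same goat numbers occur in both sets, so these overlaps also hold goat differences. The change between sets was tested with limma on the genes listed in both, with tables that had been normalized separately. It passed for 0 genes after 30 min and 0 after 180 min (2 and 1 genes at an unadjusted p under 0.05), and with the goat number as a block for 0 and 0 genes (7 and 6 at an unadjusted p under 0.05). Listing in both sets, nearly always in the same direction, had largely selected such differences out, so these counts do not show that the response was the same in both sets. The change was smaller in size in the 6D set for 465 of 647 genes after 30 min and 368 of 709 after 180 min. These counts were not tested, the genes are not independent, and the 6D libraries held fewer counts, so they do not show a weaker response.

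Between blood and muscle, 78 genes were listed in the 30 min tables of blood and the 24H set, 62 in the same direction (independent lists 140), and 34 in those of blood and the 6D set, 26 in the same direction (31.8). For 180 min, 177 genes were listed in blood and the 24H set, 118 in the same direction (246), and 151 in blood and the 6D set, 84 in the same direction (203). At 180 min, 4 genes were called in blood and the 24H set, all higher in both (independent lists 1.99), and 1 in blood and the 6D set. These independent lists were divided by the smaller number of genes adjusted, 12649 and 16947 at 30 min and 9944 at 180 min. A larger divisor would lower them, so numbers shared below them do not show that blood and muscle share fewer genes than chance.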

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

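The tests of few control goats for ASIP, of a common factor for neutrophil markers, of slow fibres, and of other splits of the samples were chosen only after the result was seen, as were the tests with 10, 20 and 80 length bins.

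In 12 of 265 groups of values, from the genes tested, the library totals and the shares of counts in listed genes (4.53%), a goat stood apart from the others of its group, and chance gives about 1 in 20. In blood, control goat 8 had the lowest NFKBIA (437 normalized counts, next 716) and CEBPB (1038, next 1711) of 7 controls, and 180 min goat 10 was listed with 0 normalized counts of INHBB, where the next goat had 13.2. In muscle of the 24H set, control goat 7 had the lowest PIK3R1 (374) and the highest RPS29 (30389) and PDK4 (50745, next 17188), and control goat 8 the lowest MDK (9.35) and SLC7A8 (28.6). Among transported goats, LIPG was lowest in 30 min goat 26 (95.2), PSAT1 highest in 180 min goat 10 (317, next 23.2), ASIP highest in 180 min goat 14 (143) and PARP14 lowest in 180 min goat 12 (23.6).

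The oxidative phosphorylation and ribosomal protein genes of muscle at 30 min in the 24H set, 54 in all, were lower in transported goats with a median log2 change of -0.48. Their median length in the tables is 510.5 bases against 1897 for all listed genes, and log2 change went with length (Spearman rho = 0.23 across genes). Random lists matched on length had a median of -0.39, so other short genes were lower too. The members lay at percentile 0.9 to 1.58 of these lists over 10, 20, 40 and 80 length bins. Genes drawn at random may vary together less than these members do, which would make the percentile too extreme. Length is therefore not excluded as a cause. By the bound set a single library did not account for them, since 34 of 52 members passed without 30 min goat 23, the fewest of the 18 libraries. The genes had been selected with all goats included, and the counts of this comparison fell strongly without some single goats. Reliance on a few goats is therefore not excluded. Fewer slow fibres in the samples may still have contributed: 0% of the oxidative phosphorylation list was listed in the 180 min table, where slow fibre genes were lower by a median of 0.74 against 0.85 at 30 min, and this slightly smaller drop keeps it open beside an effect of transport.

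ASIP was lower after 180 min because of few control goats: 3 of 9 controls, goats 2, 5 and 7 in both muscle sets, had 2308 to 2752 and 1945 to 2169 normalized counts. The other controls had at most 23.3 and 22, and the highest transported goats 143 and 54. Such a pattern could come from a heritable difference between goats that fell unevenly between the groups, which no label tests.

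Neutrophil markers in blood at 180 min may reflect a higher share of neutrophils or a change within them. Of 12 listed markers 0 deviated from the mean of the others past an adjusted p of 0.05 (largest ALPL, 2.43 ± 0.73, adjusted p = 0.052), but the intervals are too wide to show a common factor, so the share and the state of the cells cannot be told apart. No single library accounted for them by the bound set, since 3 of 6 markers, exactly at that bound, passed without control goat 1, 4 or 6 or 180 min goat 15 or 16. These genes too had been selected with all goats included, so reliance on a few goats is not excluded.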

How the results depend on the processing

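Scaling to the library total, the tests adjusted over all genes, DESeq2 with each goat left out and the direct 180 min against 30 min test were chosen after the data were seen. DESeq2, TMM and expression filtering on all genes were not run, since selected genes alone were used. Of 732 results for 122 genes chosen by the rule, over 6 settings each, 681 kept direction and side of the threshold, 49 kept direction but no longer passed, and 2 reversed: CAPN1 (-0.14) and FOS (-0.17) in blood at 180 min with libraries scaled to the total of the listed genes. In 22 cases a gene no longer passed without one of the goats. These were FOS and TSC22D3 in blood at 30 min and LCK, INHBB and PER1 in blood at 180 min. In muscle of the 24H set they were FOSL2, MB, TM4SF18, RF00012, PPP1R3A, PARP9, PRKAA2, TEF, MYOM1, IER2 and PDK1 at 30 min and PSAT1, SLC7A8, TSC22D3 and TRIM63 at 180 min, and in the 6D set TSC22D3 and TRIM63 at 180 min. The selection of the listed genes sets that total, and scaling to the library total kept both directions. Where not stated otherwise below, the cause was not tested.

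For genes past limma within the table, the authors' adjusted p gave 5, 70, 1528, 282, 3 and 119 in place of 19, 355, 3195, 1266, 1 and 765 for blood 30 min, blood 180 min, muscle 30 min 24H, muscle 180 min 24H, muscle 30 min 6D and muscle 180 min 6D. At an adjusted p of 0.01 the counts were 7, 9, 7, 52 and 21 (not muscle 30 min 6D), and at a log2 change of at least 1 they were 308, 252 and 233 for muscle 30 min 24H, 180 min 24H and 180 min 6D. Scaling to the total or upper quartile gave 8 and 12 for blood 30 min and 2 and 2 for muscle 30 min 6D, and the exact rank test 0 for both. With 4 against 7 goats in blood 30 min the smallest p this rank test can give is 0.00606. All 5 called genes had that p, so the 0 there does not speak against them. Adjusted over all genes, edgeR gave 0, 8, 12, 24, 0 and 12 and limma 0, 9, 21, 28, 1 and 7, and DESeq2 127 for blood 180 min. Leaving out each goat gave 7 to 28, 65 to 407, 1463 to 3669, 562 to 1382, 1 to 72 and 256 to 1089 for limma, and 5 to 12, 67 to 239, 283 to 2727, 163 to 510, 1 to 7 and 63 to 285 for DESeq2. Without muscle control goat 9, whose labels disagree, limma gave 1721, 748 and 414 and DESeq2 385, 228 and 77 for muscle 30 min 24H, 180 min 24H and 180 min 6D. DESeq2 fell to 283 in muscle 30 min 24H without 30 min goat 19 or 23 and 291 without control goat 7, and rose to 2727 without control goat 8.

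The percent higher was 100 by the authors' p and 75 scaled to the total in blood 30 min. It was 8.79 and 15.5 by total and upper quartile in blood 180 min. It was 51.1, 57.1, 47.4 and 42.5 by the authors' p, 0.01, log2 change of at least 1 and upper quartile in muscle 30 min 24H. For muscle 180 min 24H it was 52.8, 59.6, 48.4, 63.9 and 48.9 by the authors' p, 0.01, mean of at least 10, total and rank test. For muscle 180 min 6D it was 52.1, 66.7, 46.4 and 50.5 by the authors' p, 0.01, mean of at least 10 and rank test. Leaving out each goat gave 75 to 100, 67.1 to 88.5, 50.0 to 54.7, 41.1 to 48.0, 25 to 100 and 40.03 to 48.8, and the 25 was without 30 min goat 19 in muscle 30 min 6D. With members of a mean of at least 50, lists that passed went from 2 to 1 in blood 180 min and 3 to 1 in muscle 30 min 6D. Genes called at both times in the 24H set went from 64 to 11 at 0.01. With the goat number as a block the difference between muscle sets passed for 0 and 0 genes, as without it (7 and 6 against 2 and 1 at an unadjusted p under 0.05). The block was tried on that difference alone, over genes whose selection in both sets had largely removed such differences. In blood, recovery of simulated 2-fold changes by limma was 5% at 180 min and 16.7% at 30 min, against 88% in muscle 30 min 24H, and the cause was not tested.

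Other splits of the samples into groups of the same sizes, 100 drawn with the real one included, gave as many limma genes in 2 (blood 30 min, real 19, highest other 194), 1 (blood 180 min, 355, 4), 1 (muscle 30 min 24H, 3195, 2091), 1 (muscle 180 min 24H, 1266, 40), 5 (muscle 30 min 6D, 1, 3) and 1 (muscle 180 min 6D, 765, 5). The genes were selected on the real split, so chance cannot be excluded by these counts, and it was not excluded for muscle 30 min 6D. In blood 30 min another split gave 194 genes, and the cause was not tested.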

Other observations

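These groups were picked out only after the result was seen. B cell markers were on the lower side in several tables. In muscle of the 6D set they were listed as 0 higher and 6 lower after 30 min (Fisher's exact test, adjusted p = 0.056, 0 called, 0 past limma, 3 adjusted over the list alone) and as 0 higher and 5 lower after 180 min (adjusted p = 0.12, 1 called, 3 past limma, 1 adjusted over the list alone), and neither split passed. In the same muscle set monocyte and macrophage markers after 30 min were listed as 0 higher and 5 lower (adjusted p = 0.094, 0 called, 0 past limma, 0 adjusted over the list alone). Heat shock chaperones after 180 min in the 6D set were listed as 4 higher and 1 lower (adjusted p = 0.28, 1 called, 2 past limma, 1 adjusted over the list alone).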
